A study of Mus musculus with 18 samples.

How the data were processed

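The series measured where CLK, the clock transcription factor that binds DNA together with BMAL1, was found on chromatin in the livers of adult C57BL/6 mice kept in alternating light and dark. Crosslinked liver nuclei were either digested with micrococcal nuclease (MNase), which cuts between nucleosomes, or sonicated, and the chromatin was immunoprecipitated with an antibody against CLK and sequenced, per the labels' protocols. The time points were ZT06 and ZT22, counted in hours from lights on. Per the series design text, MNase-digested libraries carried inserts of the length of a single nucleosome and sonicated libraries mostly longer inserts, and both kinds of chromatin came from the same mice. The labels give 18 libraries in 6 groups of 3, with mouse numbers 28, 29 and 30 in every group: CLK ChIP on MNase-digested chromatin, CLK ChIP on sonicated chromatin and input of sonicated chromatin, each at both times. Groups were taken from the sample titles.

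The authors deposited a table of 3217 CLK:BMAL1 sites, with the peak's start and end, a surrounding region of 3 kb and 1 of 5 location classes per site. How the sites were called and which gene annotation was used is not given in the sources used here. The second deposited table holds mean profiles in a unit of signal: for each library and each of 2 sets of sites, values at successive positions across the 3 kb region. The sets are named for 3216 sites and for the top 400 sites. The first is 1 site short of the site table, and the rule that chose the top sites is not given in the sources used here. Values ranged from 1.07 to 22.9. The genome build was mm9, and CASAVA 1.7 and Bowtie were used, per the submitters' processing notes. How fragments were extended, filtered and scaled between libraries is not given in the sources used here, so the deposited signal of different libraries was compared mainly through ratios within a library. Of the 52 rows of profiles, 16 belong to 8 library names that match no sample of the series, and these were not used in any step. By their names these are inputs of MNase-digested chromatin at both times, with mouse numbers that no sample carries, so MNase-digested ChIP is described without a background of its own. Positions were taken as spaced by 10 bp and centred on the peak's midpoint, which the number of values over 3 kb implies but no source states.

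Because each profile is a mean over sites, no value per site was analysed here. The tests fixed before the data were examined were meant for sites; they were run on the positions of the profile instead. Signal values were changed to log2(signal + 1), and limma was fitted to the 12 ChIP libraries in 4 groups, without a block for the mouse, for 5 contrasts: the times within each kind of chromatin, the kinds of chromatin within each time, and the difference between the 2 time effects. CLK ChIP on sonicated chromatin and its input were fitted in the same way, per time. Positions with a Benjamini-Hochberg adjusted p under 0.05 were counted as called, and their share of all positions is given in percent. A log2 change is on the log2(signal + 1) scale, which understates changes at low signal. Neighbouring positions share fragments, so this share describes the extent of a difference along the region and not a number of independent findings. In the fit of the 12 ChIP libraries over all sites limma estimated 1 common variance for all positions. It did so also for ChIP against input at ZT22 over all sites, and in several fits with libraries left out. This makes single p-values very small, and for this reason p-values of single positions are not printed. Over 100 simulated sets of unchanged groups with the correlation of the real residuals, any position was called in 3 to 7% of the sets, depending on the contrast and the set of sites. In further simulations 150 positions were raised in sonicated chromatin at ZT06, in equal parts by 0.25, 0.5 or 1 on the log2 scale. The test of the times in sonicated chromatin recovered 81.2% of the changes of 0.25 over all sites, and 32% over the top sites. Changes of 1 were recovered in 100% and 99.3%. The larger changes ease the adjustment of p-values, so the recovery of 0.25 does not hold for a profile without them. Each simulated library had the same spread, whereas the real sonicated ChIP libraries varied more at ZT22 than at ZT06. These rates therefore do not vouch for contrasts that contain sonicated ChIP at ZT22. The fits of ChIP against input were not simulated.

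The windows were set after the profiles had been seen: the centre, within 100 bp of the midpoint (21 positions); the flanks, at least 1000 bp away (100 positions); and the shoulders, 150 to 300 bp away. For each library the log2 ratios of centre to flanks, shoulders to flanks and centre to shoulders were taken, which no single scaling factor per library changes. Groups of 3 were compared with an exact two-sided permutation test, which cannot give a p under 0.1, and pairs from the same liver with an exact two-sided sign-flip test, which cannot go below 0.25 for 3 pairs or 0.03125 for 6. The 3 ratios gave 51 tests for centre to flanks, 51 for shoulders to flanks and 42 for centre to shoulders, which formed 1 family for Benjamini-Hochberg adjustment. Beyond the mouse number the labels do not say whether libraries come from separate animals, and p-values measure the spread between these samples. The mean over the sites outside the top set was computed from both deposited profiles, taking the top sites as part of the 3216. Positions of maxima and minima were read from a running mean. Shares of sites carry exact (Clopper-Pearson) 95% intervals.

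Deposited signal values turned out to be whole multiples of a library-specific step divided by the number of sites, which gives the number of fragments that cover a position. In the top set, between 83.6% and 100% of a library's values were whole multiples within the 4 decimals printed. At the middle position over all sites, these counts ranged from 7233 to 9305 in sonicated ChIP at ZT06, from 1842 to 15340 at ZT22, from 12840 to 19360 in the inputs and from 34073 to 41250 in MNase-digested ChIP. The signal of 1 fragment differed 13.0-fold between the sonicated ChIP libraries. The shallowest was mouse 30 at ZT22, where the exact Poisson 95% interval at the middle spans 4.6% either way over all sites and 10.3% over the top sites. These intervals cover counting error only. Coverage is not a count of independent reads per site, so no count model was used.

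Mouse numbers pair the libraries of 1 time, since the design text takes MNase-digested and sonicated chromatin from the same mice. Their deviations from the group means did not follow the number throughout: between MNase-digested and sonicated ChIP over all sites the correlations across positions were between -0.0028 and 0.32 at ZT06 and between -0.67 and -0.38 at ZT22. Across times the number marks no shared animal that a source states, and same-numbered MNase-digested libraries gave -0.71 for mouse 30. The fits with a block are among the alternatives.

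Alternatives fixed before the data were examined were 2 other pseudocounts, equal medians, quantile normalization, an adjusted p of 0.01, leaving out each mouse number and a block for the number. Other windows, leaving out the ZT22 libraries of mouse 30, a block for the liver, further settings for the comparison with input, and subsets of the sites were added after the data were seen. The site coordinates are those of mm9, while the gene table used here is of assembly GRCm38.p6, so no site was given a gene name. The gene lists and the rule for named genes, fixed before the data were examined, could therefore not be applied. The signal by location class, also fixed before, was not computed because the profiles hold no value per site. The single sites that are named were chosen after their values were seen. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.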

Results

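CLK ChIP signal was profiled around CLK:BMAL1 sites in mouse liver at ZT06 and ZT22, on MNase-digested and on sonicated chromatin, with input of the sonicated chromatin as background. Each of the 6 groups held 3 libraries, numbered as mice 28, 29 and 30. No source used here says that a number stands for the same animal at both times, and livers are counted separately for each time. The design asks how the CLK signal at these sites depends on the time of day and on how the chromatin was cut. Each value below is a mean over sites of 1 library, with the spread given over the 3 libraries.

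Of the 3217 sites, 1623 lay within genes outside the TSS class, 50.5% (exact 95% interval 48.7 to 52.2%). Introns held 1412 sites, 43.9% (42.2 to 45.6%), and other parts of gene bodies 6.56% (5.73 to 7.47%). Transcription start sites (TSS) accounted for 583 sites, 18.1% (16.8 to 19.5%). The 1011 intergenic sites made up 31.4% (29.8 to 33.1%), of which 717, 22.3% of all sites, lay more than 10 kb from a gene by the class name. Sites were found on 20 chromosomes, with the fewest, 10, on chromosome X. Peaks had a median width of 309 bp and ranged from 40 to 719 bp. The widest, site Koike_CLKBMAL1_P0001 in the TSS class, spanned chromosome 7 from 52960041 to 52960760 in mm9, a width of 719 bp. Because 630 sites (19.6%) lay in clusters whose 3 kb regions overlap, the outer parts of the mean profiles also contain neighbouring sites. The largest cluster held 6 sites on chromosome 1, the first starting at 193268131 and the last ending at 193270650, all in the class more than 10 kb from a gene.

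**Figure D1:**
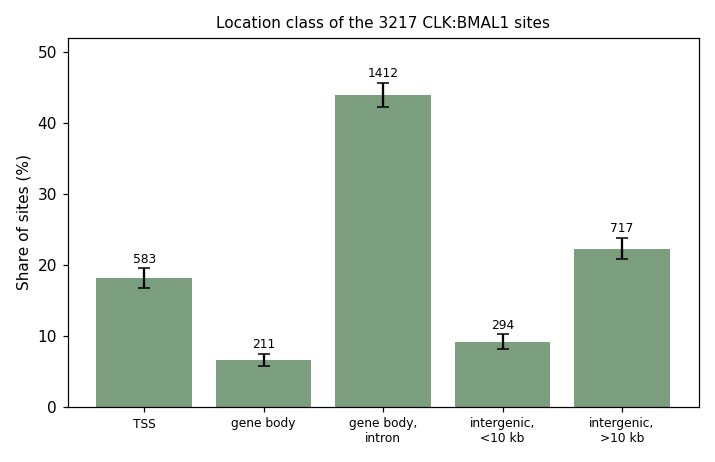
Share of the 3217 CLK:BMAL1 sites in each location class as the authors assigned it, in percent, with exact 95% binomial intervals as bars and the number of sites above each column. Introns hold 1412 sites and TSS 583.

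At ZT06, CLK ChIP on sonicated chromatin rose to a peak at the middle of the sites, well above the input. Over all sites the signal was 8.12 ± 0.67 (SD, n = 3) at the centre and 2.57 ± 0.10 in the flanks, a ratio of 3.15 ± 0.14. In the input of the same livers the ratio was 1.27 ± 0.03, so that a small central rise was also present without immunoprecipitation. At the top 400 sites the ChIP ratio was 5.77 ± 0.33 and the input ratio 1.35 ± 0.03. The ChIP peak over all sites was 360 ± 10 bp wide at 50% of its height. Relative to its own input, the log2 ratio of centre to flanks was higher by 1.31 ± 0.04 (SE) over all sites and by 2.10 ± 0.06 over the top sites, in each of the 3 livers (exact two-sided sign-flip test, p = 0.25, the smallest that 3 pairs allow; adjusted p = 0.32 in a family of 51, 51 and 42 tests of 3 ratios). With limma, 72.6% of the positions over all sites differed from input at an adjusted p under 0.05. Higher were 22.4%, among them all 21 central positions, and 50.2% were lower, whereas with equal medians 27.1% were higher and 2.68% lower. Without mouse 28 the shares were 19.1% higher and 9.03% lower, and without mouse 29 they were 20.4% and 22.4%. At the top sites 29.8% of positions were higher and 1.00% lower, and with equal medians 28.4% and 7.36%.

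At ZT22 the centre of the sonicated ChIP profile over all sites stood out little more than that of the input, except in mouse 30. Over all sites the ChIP ratio of centre to flanks was 1.42 ± 0.29 (SD, n = 3) against 1.23 ± 0.05 in the input. Relative to the own input, centre to flanks was 1.03-fold in mouse 28, 1.01-fold in mouse 29 and 1.43-fold in mouse 30. At the top sites these values were 1.39-fold, 1.06-fold and 2.43-fold. The mean log2 difference was 0.19 ± 0.16 (SE) over all sites and 0.61 ± 0.35 over the top sites (exact two-sided sign-flip test, p = 0.25; adjusted p = 0.32). With limma, 0 positions were called in either set, with 41.5% of positions over all sites and 9.70% over the top sites at an unadjusted p under 0.05. Over all sites the median position was lower in ChIP, by -0.17 on the log2 scale, and the unadjusted share was 8.03% with a block for the liver, 0% without mouse 28, 1.34% without mouse 30 and 2.01% with equal medians. Without mouse 29, 58.9% of positions over all sites were called, all lower in ChIP, with a median change of -0.25 on the log2 scale. This smaller fit used 1 common variance for all positions. It compared levels whose scaling is not known, so the share is not evidence of less CLK at the sites. Over both times, the ChIP ratio exceeded that of the input in 6 of 6 livers (exact two-sided sign-flip test, p = 0.03125, the smallest that 6 pairs allow; adjusted p = 0.14).

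**Figure D2:**
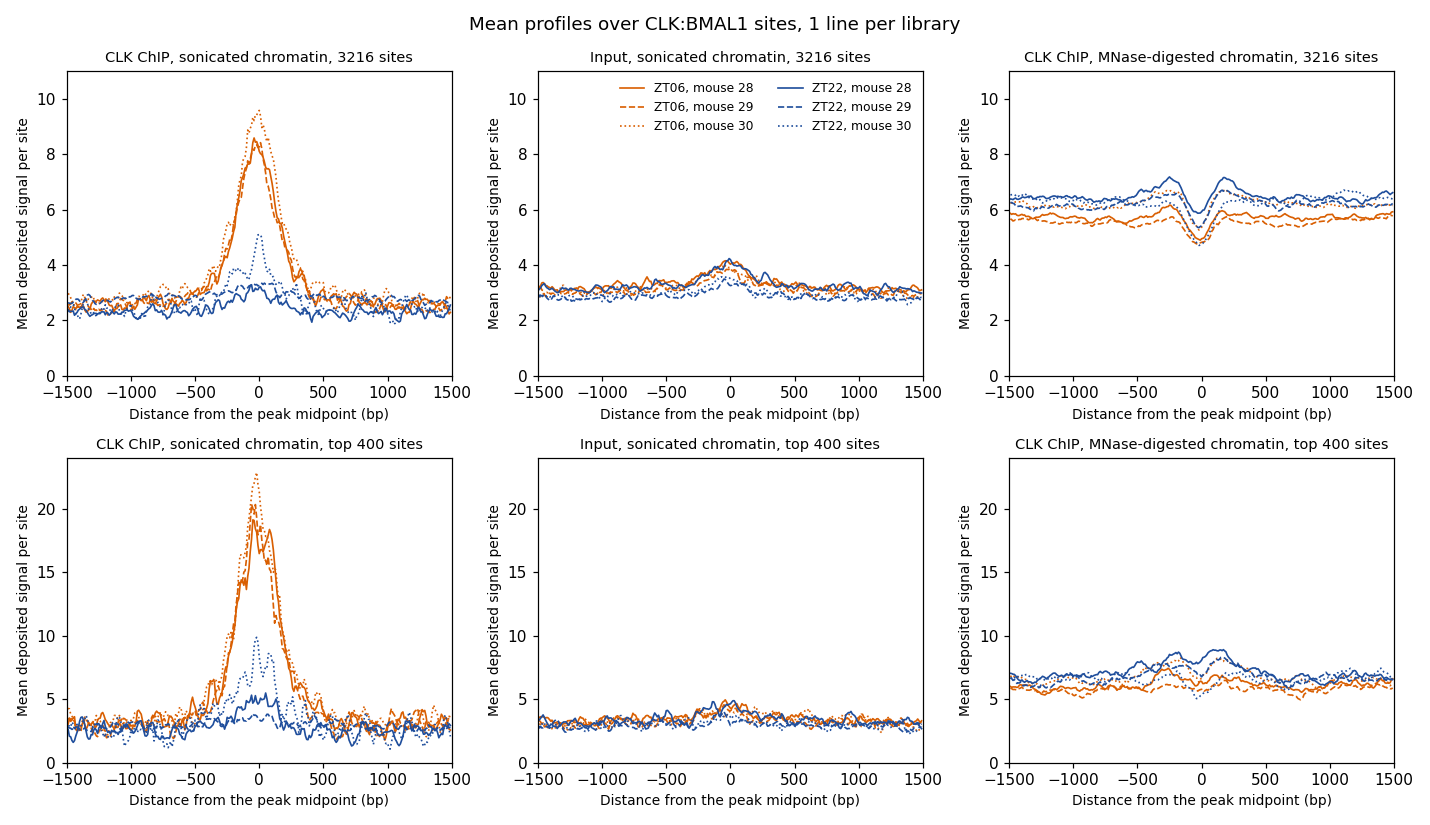
Mean deposited signal per site (vertical axis) against the distance from the peak midpoint in bp (horizontal axis), 1 line per library, with ZT06 in orange and ZT22 in blue and the line style giving the mouse. Upper panels show the 3216 sites and lower panels the top 400; sonicated ChIP at ZT06 peaks at the middle, the inputs rise slightly, and MNase-digested ChIP over the 3216 sites dips.

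In sonicated chromatin, the central CLK signal was higher at ZT06 than at ZT22, over all sites and over the top sites. The signal at the centre of all sites was 8.12 ± 0.67 at ZT06 and 3.49 ± 0.60 at ZT22 (SD, n = 3), while the flanks were at 2.57 ± 0.10 and 2.46 ± 0.24. Relative to the flanks, the centre was 2.24-fold higher at ZT06 over all sites (log2 difference 1.16 ± 0.17, SE) and 2.94-fold higher over the top sites (1.56 ± 0.37). All 3 libraries at ZT06 lay above all 3 at ZT22 in both sets. The exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 allow, and an adjusted p of 0.20. The input showed no such difference, at 0.04 ± 0.04 over all sites and 0.07 ± 0.06 over the top sites on the log2 scale (exact permutation test, p = 0.4). With limma, 32.4% of the positions over all sites and 47.2% over the top sites were higher at ZT06 and 0% lower, including all 21 central positions. Around the middle the called stretch ran without a gap from 450 bp on one side to 380 bp on the other over all sites, and from 420 to 410 bp over the top sites. The median position changed by 0.12 on the log2 scale over all sites and by 0.30 over the top sites. With equal medians, 29.1% of positions over all sites were higher and 6.69% lower, and 26.8% and 2.34% over the top sites. Without mouse 29 the share over all sites was 54.5%, and without mouse 28 that over the top sites was 25.4%. After quantile normalization, which gives every library the same set of values and so levels the peaks, 0 positions were called by limma, with 4.68% and 0.67% at an unadjusted p under 0.05.

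In MNase-digested chromatin, CLK ChIP dipped at the middle of the sites, between higher shoulders, at both times. The signal at the centre of all sites was 5.27 ± 0.39 at ZT06 and 5.62 ± 0.56 at ZT22 (SD, n = 3), below the flanks at 5.85 ± 0.27 and 6.35 ± 0.18. The centre lay below the shoulders in 6 of 6 libraries, by -0.22 ± 0.02 on the log2 scale (SE; exact two-sided sign-flip test, p = 0.03125; adjusted p = 0.14), and below the flanks in 6 of 6, by -0.17 ± 0.04. The lowest point lay between 10 and 30 bp from the midpoint in every library, with the farther shoulder maximum at ZT06 250 ± 10 bp away. At the top sites the ratio of centre to flanks was 1.04 ± 0.04 at ZT06. At ZT22 it was 1.22 in mouse 28, 1.13 in mouse 29 and 0.81 in mouse 30, a mean of 1.05 ± 0.21. Between ZT06 and ZT22 the centre relative to the flanks differed by 0.03 ± 0.10 (SE) over all sites and 0.01 ± 0.18 over the top sites on the log2 scale, within the spread of the libraries (exact two-sided permutation test, p = 1 in both sets). The sign turned without mouse 30, to -0.09 and -0.19, and without mouse 28 the difference was 0.09 and 0.11. With limma, 0 positions were called in either set, and 0 had an unadjusted p under 0.05. The fit shares its spread with sonicated ChIP: at the middle of all sites the SE was 0.076 for the times in either chromatin. Over all sites, libraries of a group differed by a mean absolute log2 difference of 0.19 to 0.27 in sonicated ChIP at ZT22. In MNase-digested ChIP it was 0.05 to 0.17. The absence of called positions is therefore not evidence that MNase-digested profiles were unchanged. All ChIP libraries of mouse 30, sonicated ones included, were also left out. Then 34.1% of positions over all sites and 19.7% over the top sites had an unadjusted p under 0.05, and still 0 were called. Leaving out the sonicated ones also changes the spread shared by the fit, so this rise cannot be ascribed to the MNase-digested libraries alone. Without only the ZT22 libraries of mouse 30, in the fit of all ChIP libraries, these shares were 0.67% and 1.34%, and 0 were called.

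**Figure D3:**
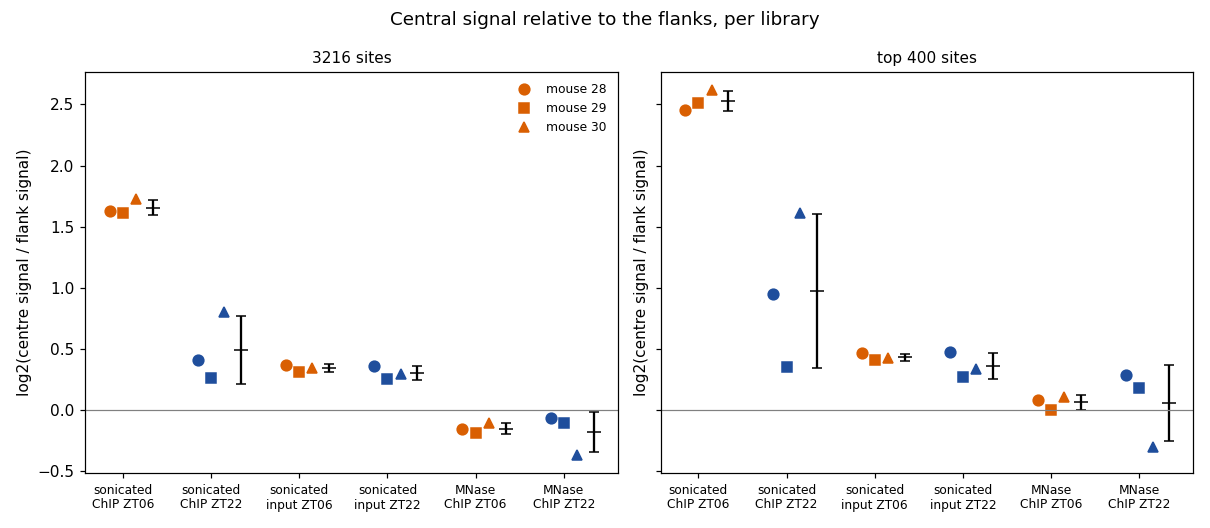
Log2 ratio of the signal within 100 bp of the midpoint to that at least 1000 bp away (vertical axis) per library, for 3216 sites (left) and the top 400 (right); symbols give the mouse, colours the time, and the bars beside them the mean ± SD of 3 libraries. Sonicated ChIP at ZT06 lies above every other group in both sets, and at ZT22 mouse 30 is the highest of sonicated ChIP and the lowest of MNase-digested ChIP.

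Over all sites at ZT06, MNase-digested and sonicated chromatin of the same livers gave opposite shapes, a dip and a peak; at the top sites the MNase-digested centre was level with the flanks. The centre relative to the flanks was lower in MNase-digested chromatin by a log2 difference of -1.81 ± 0.01 (SE) over all sites and -2.47 ± 0.05 over the top sites. At ZT22 the difference was -0.67 ± 0.25 over all sites and -0.92 ± 0.52 over the top sites, and without mouse 30 it was -0.42 in both sets. The centre was lower in MNase-digested chromatin in 6 of 6 livers over both times (exact two-sided sign-flip test, p = 0.03125; adjusted p = 0.14). On the deposited scale the levels themselves differed, with the median position higher in MNase-digested chromatin by 0.84 at ZT06 and 1.05 at ZT22 on the log2 scale over all sites. By limma on that scale, 87.3% of the positions were higher and 9.03% lower at ZT06, and 100% were higher at ZT22. The lower ones at ZT06 formed 1 stretch from 150 bp on one side to 110 bp on the other. At the top sites 74.6% were higher and 15.4% lower at ZT06, and 97.3% were higher and 0% lower at ZT22. With equal medians more positions over all sites were called lower than higher. At ZT06, 18.4% were higher and 28.8% lower, and at ZT22 1.34% and 10.4%. At the top sites it was 2.01% and 27.8% at ZT06 and 0 called by limma at ZT22, with 16.1% of positions at an unadjusted p under 0.05. Whether levels of the 2 kinds of library can be compared depends on a scaling that is not known.

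The change between ZT06 and ZT22 differed between the 2 kinds of chromatin. The log2 ratio of centre to flanks of MNase-digested minus sonicated chromatin was lower at ZT06 than at ZT22 by -1.14 ± 0.25 (SE) over all sites and by -1.55 ± 0.52 over the top sites. All 3 livers at ZT06 lay below all 3 at ZT22 in both sets (exact two-sided permutation test, p = 0.1, the smallest possible; adjusted p = 0.20). With limma, the time effect was lower in MNase-digested than in sonicated chromatin at 42.1% of positions over all sites and at 48.2% over the top sites, including all 21 central positions, and higher at 0%. The called stretch around the middle ran from 620 to 390 bp over all sites and from 420 to 410 bp over the top sites. With equal medians, 24.4% of positions over all sites and 21.4% over the top sites were lower, and 2.34% and 0.67% higher. Without mouse 28 the shares were 21.7% and 22.7%, and at an adjusted p under 0.01 that over the top sites was 25.4%. After quantile normalization 0 positions were called by limma, with 2.34% at an unadjusted p under 0.05 in each set.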

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

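All tests that bear on the explanations in this part were chosen after the results had been seen. The change from ZT06 to ZT22 differed between MNase-digested and sonicated chromatin by limma's test of the difference, at 42.1% of the positions over all sites and at 48.2% over the top sites.

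The higher central signal of sonicated CLK ChIP at ZT06 was weighed against scaling and chromatin recovery. Scaling by 1 factor per library is argued against, since the lowest log2 ratio of centre to flanks at ZT06 was 1.61 and the highest at ZT22 0.81. Chromatin that is recovered better at the centre is argued against by the input, since ChIP minus own input was at least 1.26 at ZT06 and at most 0.51 at ZT22. A difference in immunoprecipitation between the times was not tested and stays open beside a time-of-day difference in bound CLK, which is what the groups of the design compare.

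At ZT22, mouse 30 stood apart from mice 28 and 29 in both ChIP assays: over all sites its log2 ratio of centre to flanks was the highest in sonicated chromatin, at 0.81 against 0.41 and 0.26, and the lowest in MNase-digested chromatin, at -0.37 against -0.07 and -0.11. Its sonicated library was also the shallowest. At the middle the lower 95% Poisson bound of its signal, 4.87, lay above the upper bounds of the other libraries, 3.31 in both. On the deposited scale, counting error alone does not span this gap. The scaling between libraries is not known, however, so these levels do not decide on the ratio of centre to flanks. That ratio rose with the signal of 1 fragment, which was 0.68 in mouse 29, 3.08 in mouse 28 and 8.90 in mouse 30. An effect of depth therefore stays open. The input of mouse 30 does not stand out, at 0.29 between 0.25 and 0.36, which argues against chromatin recovery in that liver for the sonicated part. Exchanged labels of its MNase-digested libraries cannot be told apart from the other explanations. Both lay nearer to the other time, as did 5 of the 6 MNase-digested libraries in all. The means to which mice 28 and 29 were compared contain libraries of mouse 30, so this count does not weigh against an exchange. Distance here is the root mean square difference between log2 profiles relative to the flanks, over the inner part of the region. It was taken to the mean of the libraries with the other mouse numbers at each time. At the top sites the sonicated ZT22 library of mouse 30 also lay nearer to ZT06, at 0.65 against 0.68 to its own time. Over all sites it did not, at 0.54 against 0.32. No other sonicated library lay nearer to the other time in either set, and exchanged labels of sonicated libraries were not tested. No biological explanation was tested, since the design gives no group that sets this animal apart.

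MNase-digested ChIP showed no central maximum above the flanks over all sites. Low depth is argued against, since at least 34073 fragments covered the middle, against at most 9305 in sonicated ChIP at ZT06. If CLK-bound fragments were diluted by other nucleosomal DNA, the excess of the top over the remaining sites might be higher at ZT06; it was 0.25 at ZT06 and 0.28 at ZT22 on the log2 scale, a difference of -0.025 ± 0.10 (SE). This value rests on mouse 30, whose excess at ZT22 was 0.08 against 0.42 and 0.33: without this mouse the difference was -0.13 ± 0.05, and without mouse 28 it was 0.03 ± 0.13, so the explanation stays open. The insert of single-nucleosome length and a lack of CLK-bound nucleosomes stay open as well, and so does a dip that MNase-digested chromatin shows without immunoprecipitation: profiles named as inputs of such chromatin are in the deposited table, but they match no sample of the series and were not used here.

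With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. For MNase-digested against sonicated chromatin and for ChIP against input, the splits ignore the pairing by liver. They exchange libraries between livers as well as within them. Where the groups differ strongly, every other split mixes them, which widens the spread within groups and lowers the calls. A real share of 0% is reached by every split whatever the data. Over all sites and the top sites, 1 of the 10 splits, the real one, gave as many called positions for the times in sonicated chromatin (32.4% and 47.2% of positions, highest other 22.7% and 1.00%), MNase-digested against sonicated chromatin at ZT06 (96.3% and 89.97%, highest other 0%) and at ZT22 (100% and 97.3%, highest other 0%), the difference of the time effects (42.1% and 48.2%, highest other 0%) and ChIP against input at ZT06 (72.6% and 30.8%, highest other 0%). For the times in MNase-digested chromatin and for ChIP against input at ZT22 the real share was 0% in limma (unadjusted p under 0.05 at 0% in both sets, and at 41.5% and 9.70% without a block; over all sites 8.03% with a block for the liver and 0% without mouse 28), which all 10 splits reach; the highest other shares were 0% and, for ChIP against input over the top sites, 3.34%.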

How the results depend on the processing

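Settings other than pseudocounts, equal medians, quantile normalization, the threshold, the mouse block and leaving out mice in the ChIP contrasts were chosen after seeing the data. Of 98 shares of called positions under settings that keep all mice or drop only the ZT22 libraries of mouse 30, 75 stayed within 1.5 times the reported one; so did 35 of 42 with 1 mouse number left out. Many of these are shares reported as 0% or 100%; without them it was 47 of 67 and 21 of 27. Of the log2 ratios of centre to flanks, 56 of 66 and 37 of 42 moved by less than 1 SD. All 14 shares of location classes among wider peaks and among 1 site per cluster stayed within the reported interval; the TSS share of sites numbered up to 400, 22.3% (18.3 to 26.6%), did not. A replicate block, for the mouse number or the liver, changed none of 20 shares by over 1.5 times; for the difference of the time effects, 39.1% of positions were called over all sites and 46.2% over the top sites with the number as block, and 39.5% and 40.8% with the liver.

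Quantile normalization, which levels peak heights by its construction, left 0 positions in limma for the times in sonicated chromatin (4.68% and 0.67% at an unadjusted p under 0.05) and for the difference of the time effects (2.34% in each set). For MNase-digested against sonicated chromatin it left 8.70% and 10.03% at ZT06 and ZT22 over all sites and 4.01% and 3.01% over the top sites, with the direction turned. Equal medians remove the difference in level between the kinds of library. In the same contrast, where positions were called, this left more of them lower than higher in MNase-digested chromatin. The shares called were 47.2% and 11.7% over all sites and 29.8% and 0% over the top sites. Without the ZT22 libraries of mouse 30 as well, these were 57.2%, 8.36%, 33.1% and 0% (limma; 16.1% and 6.35% at an unadjusted p under 0.05 where 0% were called). Equal medians gave 26.8% and 22.1% for the difference of the time effects, and 29.1% for the times in sonicated chromatin over the top sites. For ChIP against input at ZT06 over all sites they gave 29.8%, with more positions higher than lower, in place of more lower than higher. Also without the ZT22 libraries of mouse 30, they gave 31.1% for the times and 24.7% for the difference at the top sites. At an adjusted p of 0.01 the difference was called at 25.4% of positions of the top sites. Except where the construction is named, the cause was not tested.

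With each mouse number left out in turn, the shares ranged from 25.8% to 54.5% (all sites; highest without mouse 29) and from 25.4% to 45.2% (top sites; lowest without mouse 28) for the times in sonicated chromatin. They ranged from 21.7% to 60.2% and from 22.7% to 49.5% for the difference of the time effects, both lowest without mouse 28. For ChIP against input over all sites they ranged from 28.1% to 84.3% at ZT06. At ZT22 they ranged from 0% to 58.9%, highest without mouse 29. At ZT06 more positions were called lower than higher with all mice, and more higher than lower without mouse 28. The median position stayed lower in ChIP, by -0.12 with all mice and -0.09 without mouse 28 on the log2 scale. The log2 difference between MNase-digested and sonicated chromatin at ZT22 ranged from -0.82 to -0.42 over all sites and from -1.29 to -0.42 over the top sites. The difference of the time effects ranged from -1.37 to -0.99 and from -2.03 to -1.15. Without only the ZT22 libraries of mouse 30, these were -0.42, -0.42, -1.39 and -2.05. The log2 difference between the times in MNase-digested chromatin ranged from -0.09 to 0.09 and from -0.19 to 0.11. The cause was not tested.

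A centre within 50 bp gave -1.92 and -2.56 for MNase-digested against sonicated chromatin at ZT06, and a centre within 200 bp gave -1.54 and -2.19, and 1.18 and 1.95 for ChIP against input at ZT06, as a wider window takes in the slopes. The alternatives that need values per site or gene names were not run: filters on low signal, 1 site per gene, signal by location class and gene lists. A count test was not run, since the values are not counts. Depth limits mainly sonicated ChIP of mouse 30 at ZT22, with 1842 fragments at the middle over all sites and 375 over the top sites.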

Other observations

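All comparisons in this part were chosen after the data had been seen. The top sites carried more central signal than the 2816 remaining sites in every kind of library. In sonicated ChIP the log2 ratio of centre to flanks was 2.53 ± 0.08 at the top sites and 1.43 ± 0.07 at the remaining sites at ZT06 (SD, n = 3), and 0.97 ± 0.63 and 0.39 ± 0.21 at ZT22. In MNase-digested ChIP it was 0.06 ± 0.06 and -0.19 ± 0.04 at ZT06, and 0.05 ± 0.31 and -0.22 ± 0.14 at ZT22. Over both times the excess of the top sites was 0.84 ± 0.16 (SE) in sonicated ChIP, 0.26 ± 0.05 in MNase-digested ChIP and 0.09 ± 0.02 in input, in 6 of 6 libraries each (exact two-sided sign-flip test, p = 0.03125, the smallest possible; adjusted p = 0.14). The rule that chose the top sites is not known, so their excess in ChIP is not independent of that choice. At the remaining sites at ZT22, sonicated ChIP relative to its own input was 0.97-fold in mouse 28, 1.00-fold in mouse 29 and 1.27-fold in mouse 30.

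Input of sonicated chromatin was itself raised at the sites, by 0.32 ± 0.02 (SE) on the log2 scale over all sites in 6 of 6 libraries (exact two-sided sign-flip test, p = 0.03125; adjusted p = 0.14). The rise peaked 33 and 37 bp to the same side of the midpoint at ZT06 and ZT22 on average.

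The shoulders of the MNase-digested profile relative to the flanks were at 0.18 ± 0.05 (SE) over the top sites, in 6 of 6 libraries (exact two-sided sign-flip test, p = 0.03125; adjusted p = 0.14), and at 0.05 ± 0.03 over all sites, above 0 in 4 of 6 (p = 0.19 by the same exact test; adjusted p = 0.32).

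Sites numbered up to 400 in the deposited list had a median width of 389 bp, against 309 bp for all sites. Of the intergenic sites within 10 kb of a gene, 26.2% (exact 95% interval 21.3 to 31.6%) lay in a cluster of overlapping regions, against 16.9% (14.2 to 19.8%) of those farther away. Sites of the same cluster share this property, while the intervals treat sites as independent. The intervals are therefore too narrow for this comparison. The TSS class was present in 76 clusters.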
